A study of Mus musculus with 6 samples.

How the data were processed

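RNA was measured by sequencing in 6 libraries of mouse RM1 prostate cancer cells. RM1 is a mouse prostate cancer line, and RM1536 is RM1 labelled with the fluorescent protein eCFP and the luciferase luc2, made by pooling clones 5, 3 and 6. The groups were unlabelled RM1 in culture (replicates a and b), RM1536 in culture (replicates a and b), RM1536 recovered from the femur (1 library, called bone) and RM1536 recovered from the lung (1 library). Bone and lung cells came from 1 mouse, 16 days after injection into the heart of cells stained with the dye PKH26. PKH-negative cells, which had diluted the dye by dividing, were used. Per the labels, cells were isolated by FACS and grown again in DMEM with 5% FBS until a T75 flask was 85% covered, so the bone and lung libraries are of cells cultured after recovery. Total RNA from about 5e6 cells (innuPREP kit, RIN over 6.8) was made into libraries with the NEBNext Ultra kit and sequenced on a HiSeq2500.

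The deposited table holds raw counts per gene. The submitters' processing notes name the mouse genome GRCm38, TopHat2 2.1.10, HTSeq and edgeR, without the role of each. The strand setting, the HTSeq mode and the annotation release are not given in the sources used here. The table has 23792 entries. An entry with a blank name (0.00626% to 0.00830% of the counts of a library) was left out, which left 23791. Of these, 1710 were at 0 in all libraries and 27 had names turned into dates, 4 of which share a name with another entry. A GENCODE M21 gene has the same symbol for 23100 entries, and positions and gene types were taken from that release. Total counts were 30199663 (RM1 a), 27562047 (RM1 b), 24291590 (RM1536 a), 30303566 (RM1536 b), 22763835 (bone) and 26903505 (lung). A count of 3, used as the limit that 0 counts allow, equals 0.099 to 0.132 counts per 1e6 counts (CPM). Counting intervals are exact 95% intervals, and intervals and limits cover counting error only.

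Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by group, quasi-likelihood fit and test, all 6 libraries in 1 model with 4 groups). 13832 genes were tested and Benjamini-Hochberg (BH) adjusted p values were taken over them, with a call at 0.05. Normalization factors ran from 0.942 to 1.02. The spread came from the RM1 pair and the RM1536 pair (2 residual degrees of freedom, prior degrees of freedom 4.03, common dispersion 0.0725, biological coefficient of variation 0.269). The bone and lung libraries have no replicate and were assumed to vary like the culture duplicates. A p value covers only the spread between these duplicates, which may be technical in part. The labels do not say whether a and b are separate cultures. The duplicates differed beyond counting error, with a chi-square per degree of freedom of 89.9 in RM1 and 91.1 in RM1536. Interferon-stimulated genes had a median log2 difference of 2.59 between RM1536 a and b. That argues against repeat libraries of the same RNA for that pair. No p value covers the spread between animals. CPM values are scaled by the TMM factors, except for the sex-linked genes, Lyz2, the summed leukocyte markers and library shares, which use total counts. Log2 fold changes are given with an SE, taken as their size over the square root of the F statistic. This SE is approximate where a group is near 0. A fold against a group at 0 was taken against 3 counts over the group.

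There were 4 comparisons: RM1536 against RM1, bone against RM1536, lung against RM1536, and bone against lung. Groups, comparisons, tests, alternatives, 27 gene lists (503 entries) and the rule for named genes were set before the data were examined. Of the list entries, 22 have no entry in the table, and 1 was matched through an older symbol (Nectin2 as Pvrl2). The lists are type I interferon-stimulated genes; interferon receptors, sensors and upstream factors; MHC class I antigen presentation; cell cycle; MYC targets and ribosome biogenesis; epithelial genes; mesenchymal transition factors and markers; collagens and matrix proteins; matrix proteases and inhibitors; bone metastasis and osteomimicry genes; prostate and androgen receptor genes; cholesterol synthesis; glycolysis and hypoxia; unfolded protein response and ATF4 genes; p53 targets; NF-kappaB chemokines and inflammatory genes; oxidative stress (NRF2) genes; dormancy-associated genes; immune checkpoint ligands; markers of leukocytes, erythroid cells, lung epithelium, endothelium, stromal fibroblasts, and osteoblasts and osteoclasts; Y-linked genes; and mitochondrially encoded genes. The checkpoint list also holds Raet1e, H60b and Ulbp1, which code for ligands of an activating receptor, so its name covers them only loosely. All 27 had at least 3 tested members. Lists were tested with camera in edgeR at a preset correlation of 0.01, with BH adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run as alternatives. Members were also adjusted over the list alone. Bone against lung is 1 library against 1, so its lists have no set test there, and the median log2 fold change is given with its percentile among 10000 random lists of the same size and abundance.

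The rule named, for each comparison, the 10 genes with the highest and the 10 with the lowest log2 fold change among those called, with a mean CPM of at least 5 and with no overlap between the groups. Predicted genes were counted but not named. For bone against lung the places were filled with the largest differences at a CPM of at least 5 in the higher library, given as values. From each list the rule took up to 4 called members with the smallest p, or the 2 most abundant members as values where none was called. It also took the Y-linked genes, Xist, Ifnar1 and Ifnar2. Every called gene the rule selected is named in the report, except 1 that is not reported here. Of the abundant uncalled members, some are printed. Any other gene was chosen after its values were seen, and the text says so.

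Alternatives were DESeq2 1.42.0 size factors in edgeR, no low-count filter, a CPM of at least 5 in 2 libraries, the DESeq2 test, limma-voom (limma 3.58.1), robust dispersion, a 2-fold minimum, the replicate letter as a block, leaving out each culture library, the 4 culture libraries alone, and the mean of RM1 and RM1536 as the reference. A crossed pairing of the culture libraries as a block was added after seeing the data, as were a split of the RM1536 libraries between the sites, counts of called lists and list members under the alternatives other than the 2 list tests, and medians of lists other than the interferon-stimulated one under the alternatives. The letters a and b do not pair the groups: across genes, the a minus b differences of RM1 and RM1536 had a correlation of -0.37, and genes are not independent replicates. No group has 3 samples, so no other splits of the samples were counted.

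The tests were tried on simulated tables, 3 per comparison, with the duplicates' dispersion and 50 planted genes per fold in each. Planted genes had a mean CPM of at least 5. RM1536 against RM1 recovered 14% of planted 2-fold, 92.7% of 4-fold, 98% of 8-fold and 100% of 32-fold changes. Bone against RM1536 recovered 5.33%, 72%, 97.3% and 100% at these folds. Lung against RM1536 recovered 8%, 76.7%, 99.3% and 100%. Bone against lung recovered 2.67%, 56%, 92.7% and 100%. Unplanted genes called over the 3 tables numbered 56, 59, 61 and 61, which is more than the nominal share. A planted list of 20 genes at 2-fold was called in 3 of 3 tables, and 0 of 78 unplanted lists were called. Genes were drawn independently of each other in these tables. In the data, members of some lists moved together, with an estimated correlation of 0.912 for interferon-stimulated genes in RM1536 against RM1. The simulated lists therefore give no rate of false list calls for these data. The gene rates do not carry over either: in lung against RM1536, Col1a1 had a log2 fold change of 5.04 and was not called. Few calls in bone or lung therefore do not mean that large changes were absent. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Reads themselves were not used here, so variants, splicing and the eCFP and luc2 transcripts were not analysed here. Genes with near-identical copies (H2 class I, Oas and Ifit families) and overlapping genes have uncertain counts, because the counting settings are not given.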

Results

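Messenger RNA was measured as deposited counts per gene in 6 libraries: 2 of RM1 (unlabelled mouse prostate cancer cells in culture), 2 of RM1536 (eCFP- and luc2-labelled RM1 in culture), 1 of RM1536 recovered from the femur and 1 of RM1536 recovered from the lung of the same mouse. The bone and lung libraries have no replicate. Depth, in units of 1e6 counts, was 30.2 in RM1 a, 27.6 in RM1 b, 24.3 in RM1536 a, 30.3 in RM1536 b, 22.8 in bone and 26.9 in lung. Adjusted p values are from the edgeR quasi-likelihood test with BH adjustment over 13832 genes.

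All 6 libraries expressed the Y-linked genes. Ddx3y stood at 68.0 and 82.2 CPM in RM1, 101 and 89.6 in RM1536, 106 in bone and 114 in lung, and Eif2s3y, Kdm5d and Uty had between 15.8 and 77.2 CPM in each library. Xist had 1 read in RM1 a, 6 in bone, 5 in lung and 0 in the other 3 libraries. Mitochondrially encoded genes took 0.932% and 0.567% of the counts in RM1, 1.30% and 1.2% in RM1536, 1.83% in bone and 1.95% in lung. The culture duplicates differed from each other: 525 genes (5.27% of those at a CPM of at least 5 in either library) differed by 2-fold or more between RM1 a and b, and 573 (5.78%) between RM1536 a and b. Bone differed by that much from RM1536 a in 756 genes and from RM1536 b in 1066, and lung in 867 and 1915. Bone and lung differed in 1057 genes.

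The first comparison asks how the labelled, pooled-clone line differs from the line it was made from. Interferon-stimulated genes, which code for antiviral proteins, were lower in RM1536 in 48 of 49 members, with a median log2 fold change of -2.95. Over all genes tested, 14 members fell and 1 rose; adjusted over the list alone, 45 fell and 1 rose. Rsad2, an antiviral enzyme, had a log2 fold change of -7.31 ± 1.203 (SE, n = 2 and 2; adjusted p = 0.0291), with 266 and 489 CPM in RM1 against 4.59 and 0.259 in RM1536. Also lower were Cmpk2 (log2 fold change -6.67 ± 0.98, adjusted p = 0.0220), Lgals3bp (-3.24 ± 0.38, 0.0142) and Parp14 (-2.95 ± 0.45, 0.0246). The exception was Ifitm1, a membrane protein that restricts virus entry, which rose by 4.60 ± 0.25 (adjusted p = 0.00443), from 20.1 and 17.9 CPM to 513 and 408.

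The 18 genes of MHC class I antigen presentation had a median of -1.64. Of these, 9 fell over all genes tested and 16 fell when adjusted over the list alone. Nlrc5, a transcriptional activator of MHC class I genes, fell by 3.84 ± 0.49 on the log2 scale (adjusted p = 0.0165). Also lower were H2-Q4 (-3.78 ± 0.38, 0.0107), the immunoproteasome subunit gene Psmb8 (-3.36 ± 0.44, 0.0175) and the classical class I gene H2-K1 (-1.88 ± 0.23, 0.0156). Among 19 receptors, sensors and upstream factors of interferon the median was -0.50, with 2 lower and 1 higher (adjusted over the list alone, 6 and 1). The transcription factor gene Irf5 (-5.51 ± 0.79, 0.0206) and the double-stranded RNA sensor gene Tlr3 (-2.55 ± 0.50, 0.0441) fell, while Tmem173, which codes for the adaptor STING, rose by 1.08 ± 0.22 (0.0473). The receptor genes Ifnar1 (-0.50 ± 0.22, adjusted p = 0.252) and Ifnar2 (-0.60 ± 0.22, 0.186) did not pass. Camera adjusted p values were 1.29e-24 for the interferon-stimulated list, 1.60e-13 for MHC class I and 0.0106 for receptors and sensors. With an estimated correlation none was called (adjusted p = 0.911 for each).

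The size of the interferon difference depended on the RM1536 library. The list's median level was 99.9 and 137 CPM in RM1, 21.6 in RM1536 a and 3.27 in RM1536 b. Without RM1536 a the median log2 fold change was -4.87 and 44 members were called; without RM1536 b it was -2.19 and 13 were called. The MHC class I list had 5 called members without RM1 b and 2 without RM1536 b (median -1.22). Without RM1536 b, H2-K1, Irf5, Psmb8, Sp100 and Tlr3 missed the threshold (adjusted p 0.0531 to 0.0724). Tlr3 also missed it without RM1 a (0.0712) or RM1 b (0.0620) and under the stricter filter (0.0589). Tmem173 missed it without any 1 of the 4 culture libraries, at up to 0.223 without RM1 b, and under the stricter filter (0.0564). The receptor and sensor list lost its camera call without RM1 a (adjusted p = 0.0548).

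**Figure D1:**
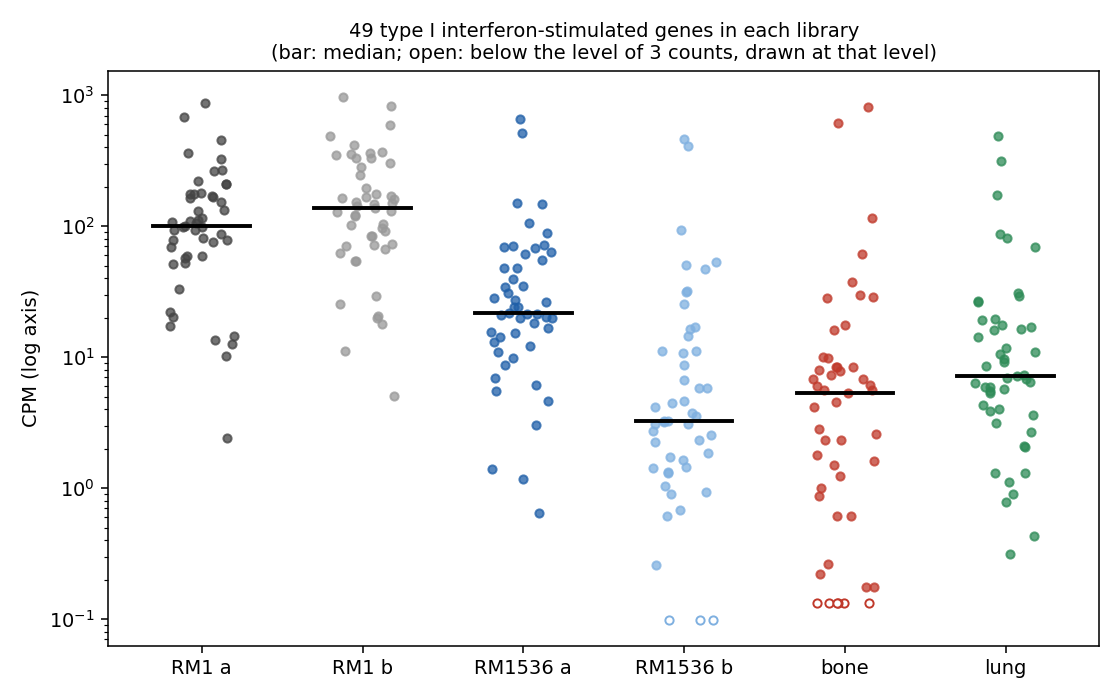
Level of each of 49 type I interferon-stimulated genes (points, CPM on a log axis) in the 6 libraries, with the list median as a bar; open points are below 3 counts and drawn at that level. Medians were 99.9 and 137 CPM in RM1, 21.6 and 3.27 in RM1536, 5.36 in bone and 7.18 in lung.

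Among called genes with a mean CPM of at least 5, the largest increases in RM1536 were in Ptgis, the prostacyclin synthase gene, and Dkk2, which codes for a secreted regulator of Wnt signalling. Ptgis (chromosome 2, 167191805 to 167240604, GRCm38) had 3 reads in RM1 against 2323 in RM1536, a ratio of 808 (95% counting interval 276 to 3922). Dkk2 (chromosome 3, 132085292 to 132180304) rose by 7.53 ± 0.48 on the log2 scale (adjusted p = 0.00576). Crabp1, a retinoic acid binding protein gene, rose by 6.71 ± 0.42 (0.00576), from 7.62 and 14.6 CPM to 1114 and 1221. Nptx1, Kcnab1, Gfi1, Stmn2 and Lox rose by between 6.12 and 6.64. Cemip (3 reads against 334, ratio 116, interval 39.4 to 566) and Casp1 (3 against 244, ratio 84.9, interval 28.7 to 414) were also higher. Pax5, a B cell transcription factor gene, had 8.79 and 26.7 CPM in RM1 and 0 reads in RM1536, at least 324-fold lower (adjusted p = 0.0164). Csn3 (-9.88 ± 0.64, 0.00576), the imprinted gene Peg3 (-8.43 ± 0.44, 0.00443), Sall1 (-7.43 ± 0.80, 0.0125), Trim54 (-7.05 ± 0.48, 0.00614), Sp100 (-6.23 ± 0.71, 0.0134) and Pax3 (-5.79 ± 0.38, 0.00576) fell. Pax5 and Sp100 missed the threshold without RM1536 b (adjusted p = 0.0554 and 0.0549), and DESeq2 did not call Pax5 (0.114) or Sall1 (0.202).

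At the Cdkn2 region of chromosome 4, which holds cell cycle inhibitor genes, transcripts were lost from RM1536. Cdkn2b (89306299 to 89311039) had 5872 reads in RM1 and 2 in RM1536, a ratio of 0.000355 (95% counting interval 4.30e-05 to 0.00128; adjusted p = 0.00443). Its neighbours were chosen after their values were seen. Cdkn2a (89274471 to 89294653) had 146 and 112 reads in RM1 and 0 in the other 4 libraries (adjusted p = 0.0130; 0.232 with DESeq2). The noncoding Gm12606 fell by 3.96 ± 0.46 (0.0140). Mtap, on the other side of Gm12606, rose by 1.83 ± 0.24 (0.0179), from 135 and 187 CPM to 577 and 569, and stood at 571 in bone and 630 in lung. Mtap missed the threshold without RM1 a (0.0606) or RM1536 b (0.0583). More distant, Klhl9 (0.04, adjusted p = 0.944) and Focad (0.02, 0.977) did not pass.

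**Figure D2:**
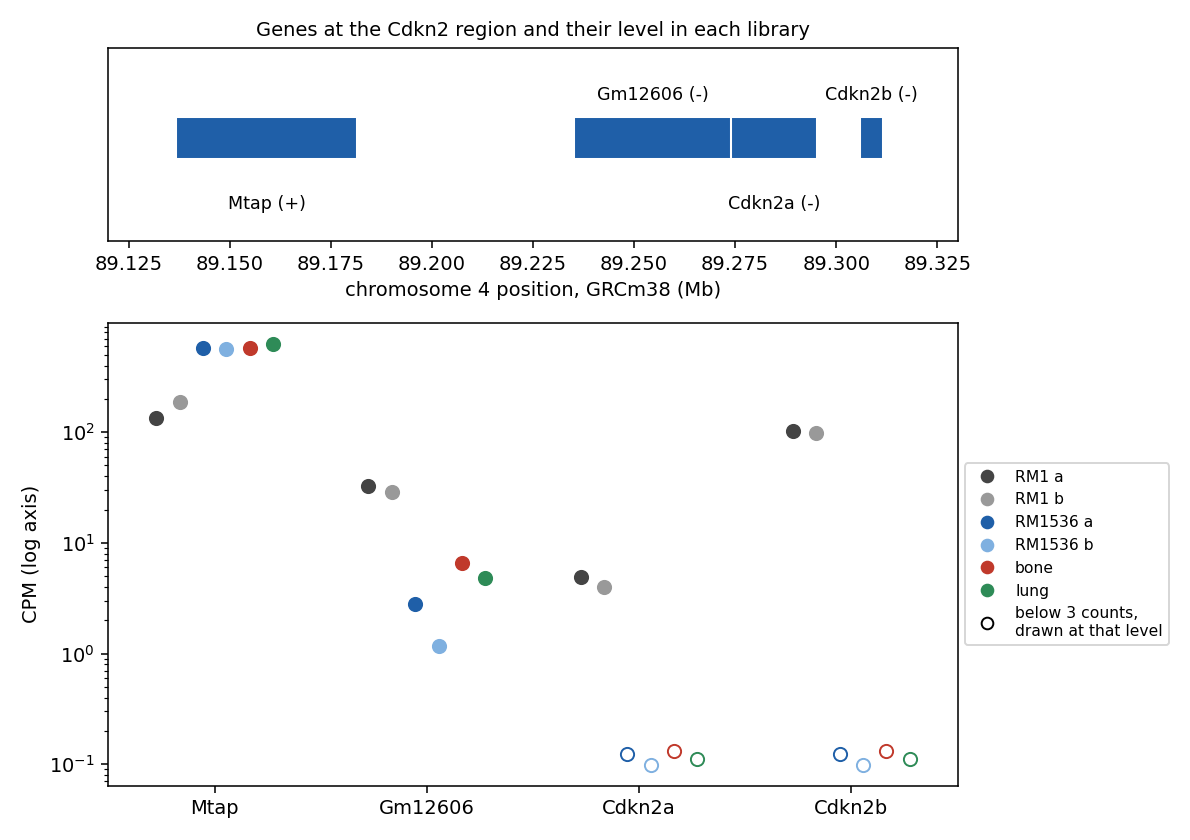
Map of Mtap, Gm12606, Cdkn2a and Cdkn2b on chromosome 4 (GRCm38, Mb) above their CPM (log axis) in the 6 libraries; open points are below 3 counts and drawn at that level. Cdkn2b stood at 103 and 99.0 CPM in RM1 and below 3 counts in each other library, while Mtap was higher in the other 4 libraries than in RM1.

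Genes of cell contact and matrix moved both ways. Of 11 epithelial genes, 3 fell over all genes tested and also when adjusted over the list alone: Krt19 (log2 fold change -4.53 ± 0.51, adjusted p = 0.0132), the tight junction gene Ocln (-2.53 ± 0.45, 0.0359), and the desmosome gene Dsp (3 reads in RM1536 against 344, ratio 0.00910, interval 0.00187 to 0.0268). The list's median was -0.18, its mean -1.24 and its camera adjusted p 0.0248 (0.911 with an estimated correlation). Among 22 collagens and matrix proteins, 3 rose and 2 fell (7 and 3 adjusted over the list alone; median 0.03, camera adjusted p = 0.0616). Lox, which crosslinks collagen, rose by 6.12 ± 0.44 (0.00614) and Col6a2 by 3.70 ± 0.49 (0.0182), while the laminin gene Lama5 fell by 4.28 ± 0.51 (0.0146) and Col5a2 had 2 reads against 575 (ratio 0.00363, interval 0.000439 to 0.0132). Among 20 mesenchymal transition genes, 1 rose and 2 fell, with Tgfbi up by 2.85 ± 0.49 (0.0318) and Tgfb1 at -1.40 ± 0.25 (0.0364) (adjusted over the list alone, 2 and 2; median 0.10, camera adjusted p = 0.407). Of 18 matrix proteases and inhibitors, Mmp2 rose by 1.93 ± 0.24 (0.0162), and Plaur (-1.62 ± 0.26, 0.0265), Adam8 (-3.17 ± 0.50, 0.0265) and Serpinb2 (-4.27 ± 0.74, 0.0335) fell (adjusted over the list alone, 2 and 3; median -0.14, camera adjusted p = 0.446). Krt19, Lox, Col6a2 and Col5a2 kept their calls under every alternative run. Without RM1536 a, 6 of the 13 genes named in this paragraph missed the threshold (Dsp, Ocln, Tgfb1, Lama5, Adam8 and Serpinb2; adjusted p 0.0545 to 0.0670). Without RM1536 b, these 6 with Mmp2 and Plaur missed it (0.0535 to 0.134). Without RM1 a, Ocln and Tgfbi missed it (0.0880 and 0.0602), and without RM1 b, Tgfbi, Tgfb1 and Serpinb2 (up to 0.0883). DESeq2 did not call Dsp (0.203). The epithelial list was not called without RM1536 b (median -0.32, adjusted p = 0.172) or without a low-count filter (0.286), and its median was -1.75 without RM1536 a and -0.37 without RM1 b. Without RM1 a, RM1 b, RM1536 a and RM1536 b in turn, the median was -0.28, -0.01, -0.63 and 0.13 for proteases, 0.64, -0.04, 0.36 and -0.15 for collagens and 0.17, 0.31, 0.24 and 0.20 for mesenchymal genes.

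Immune checkpoint ligands were lower in RM1536: 4 of 11 fell over all genes tested and 6 when adjusted over the list alone (median -1.12, camera adjusted p = 0.00250; 0.911 with an estimated correlation; 0.102 without a low-count filter). These were Cd276 (log2 fold change -2.05 ± 0.21, adjusted p = 0.0110), Lgals9 (-3.29 ± 0.40, 0.0148), Cd274, which codes for PD-L1 (-2.60 ± 0.49, 0.0410) and Pvrl2 (-1.58 ± 0.30, 0.0413). Of 19 bone metastasis genes, the integrin gene Itgb3 (1.57 ± 0.21, 0.0185) and the chemokine receptor gene Cxcr4 (3.87 ± 0.68, 0.0339) rose, and Gas6 (1 read in RM1536 against 53, ratio 0.0197, interval 0.000489 to 0.115) fell. Of 11 stromal fibroblast markers, Gsn rose by 0.97 ± 0.19 (0.0473), and Ly6a (-3.25 ± 0.38, 0.0142) and Fap (-3.82 ± 0.55, 0.0214) fell. Of 6 osteoblast and osteoclast markers, Ctsk rose by 4.30 ± 0.87 (0.0477) and Dmp1 fell by 5.32 ± 0.81 (0.0242). Single members also passed in 5 lists that were not called: Krt15 fell (-4.38 ± 0.61, 0.0198), Btg2 fell (-1.38 ± 0.26, 0.0401), Ccl7 rose (2.11 ± 0.34, 0.0276), Laptm5 fell (-3.21 ± 0.56, 0.0343), and in the NRF2 list Osgin1 fell (-2.26 ± 0.32, 0.0200) and Gclm rose (1.12 ± 0.21, 0.0392). Cd276, Lgals9 and Ly6a kept their calls under every alternative run. Of these 18 genes, 9 missed the threshold without RM1 a (adjusted p 0.0566 to 0.169), 8 without RM1 b (0.0695 to 0.234), 13 without RM1536 a (0.0542 to 0.140) and 12 without RM1536 b (0.0630 to 0.155). DESeq2 did not call Gas6 (0.108), limma-voom did not call Cxcr4, Dmp1 or Ctsk (up to 0.0943), and the stricter filter ended the calls of Cd274, Cxcr4, Ctsk, Gsn and Pvrl2 (up to 0.0693).

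Cell cycle genes lay higher in RM1536 in 30 of 32 members (median 0.64, camera adjusted p = 0.000730), with 0 members called over all genes or over the list alone; Pcna, the replication clamp gene, stood at 262 and 175 CPM in RM1 and 316 and 418 in RM1536. Mitochondrially encoded genes lay higher in 11 of 12 (median 0.88, camera adjusted p = 0.00595), with 0 called; mt-Cytb had a log2 fold change of 1.00 ± 0.28 (adjusted p = 0.104). Both lists had an adjusted p of 0.911 with an estimated correlation. The cell cycle list was not called without RM1 b (median 0.28, adjusted p = 0.249) or RM1536 b (0.29, 0.133), and its median was 1.06 without RM1 a. The mitochondrial list was not called without RM1 b (0.52, 0.122), and its median was 1.29 without RM1 a. The other lists did not pass camera, with adjusted p from 0.387 to 0.867. Their medians were 0.16 for MYC targets, 0.04 for bone metastasis genes (called 2 up and 1 down; over the list alone 4 and 3), 0.59 for prostate genes (0 and 1; 1 and 1), 0.46 for cholesterol synthesis, 0.00 for glycolysis, -0.27 for the unfolded protein response, 0.14 for p53 targets (0 and 1; 1 and 3), -0.57 for NF-kappaB chemokines (1 and 0; 1 and 2), 0.24 for NRF2 genes (1 and 1; 2 and 2) and 0.15 for dormancy genes (0 and 1; 1 and 1). They were -0.15 for leukocyte markers (0 and 1; 0 and 1), 0.88 for erythroid markers, 0.33 for lung epithelium (0 and 0; 1 and 0), -0.66 for endothelium, 0.87 for stromal fibroblasts (1 and 2; 5 and 2), -1.39 for osteoblasts and osteoclasts (1 and 1; 1 and 2) and 0.31 for Y-linked genes. Lists without counts in brackets had 0 called members. Leaving out 1 library turned the sign of some of these medians: without RM1 b to 0.43 for endothelium, 0.33 for the unfolded protein response and -0.12 for glycolysis; without RM1536 b to -0.07 for cholesterol synthesis and MYC targets, -0.38 for bone metastasis genes, -0.09 for p53 targets, 0.13 for the unfolded protein response and 0.11 for endothelium; without RM1536 a to -0.07 for dormancy genes and glycolysis; and without RM1 a to -0.01 for p53 targets. Other medians kept their sign and moved by over 1.5 times. Without RM1 a these were 1.36 for erythroid markers, 0.03 for lung epithelium, -1.28 for endothelium, 0.40 for stromal fibroblasts, -0.46 for leukocyte markers, 0.10 for Y-linked genes and bone metastasis genes, -0.60 for the unfolded protein response and 0.25 for glycolysis. Without RM1 b they were 0.38 for prostate genes, 0.28 for cholesterol synthesis, -0.32 for NF-kappaB chemokines, 0.50 for NRF2 genes, 0.26 for dormancy genes, 0.08 for bone metastasis genes, 0.57 for erythroid markers, 0.65 for lung epithelium, -0.45 for osteoblasts and osteoclasts and 0.49 for Y-linked genes. Without RM1536 a they were 0.36 for MYC targets, 0.19 for bone metastasis genes, 0.22 for prostate genes and stromal fibroblasts, -0.85 for the unfolded protein response, -1.61 for leukocyte markers, 0.21 for erythroid markers, 0.94 for lung epithelium, -1.21 for endothelium and 0.13 for Y-linked genes. Without RM1536 b they were -0.31 for NF-kappaB chemokines, -0.55 for leukocyte markers, 0.20 for erythroid markers, 0.80 for lung epithelium and 0.01 for glycolysis. Median, mean and test differed in sign for bone metastasis, prostate, p53 and dormancy genes.

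**Figure D3:**
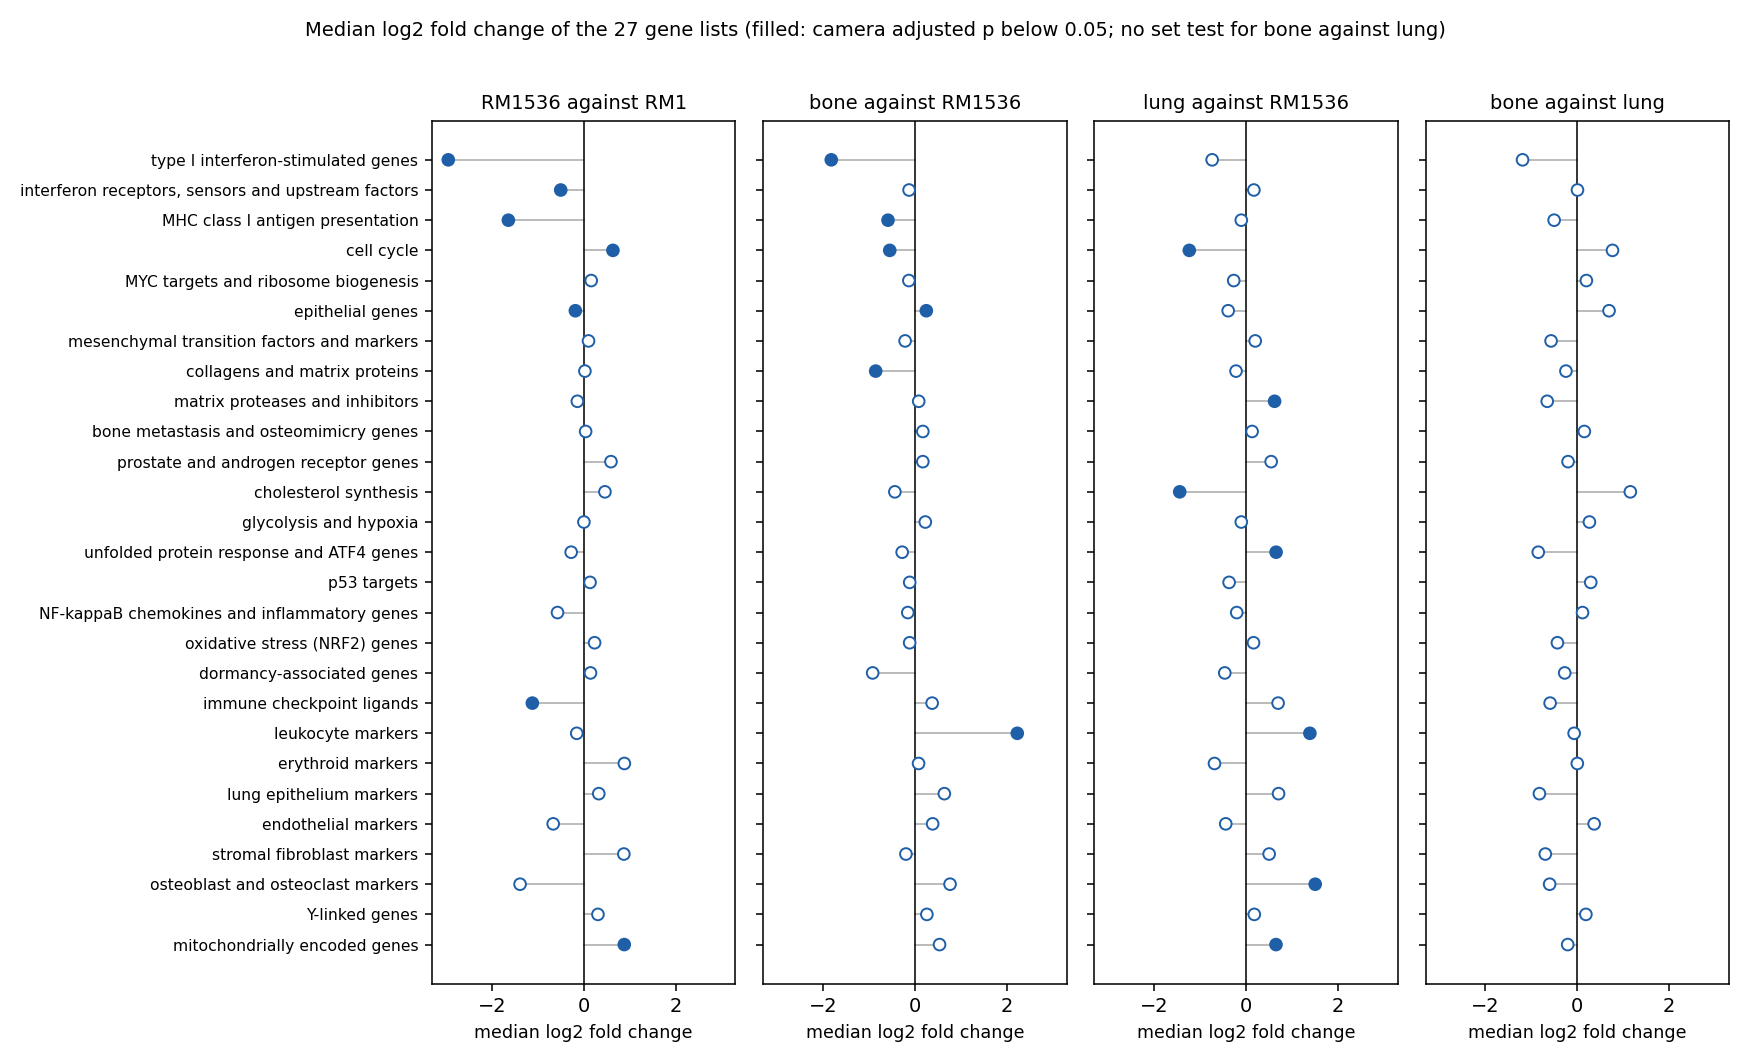
Median log2 fold change of the 27 gene lists (vertical axis) in the 4 comparisons (panels); filled points are lists with a camera adjusted p below 0.05, and bone against lung has no set test. The interferon-stimulated list lay at -2.95 in RM1536 against RM1, -1.82 in bone and -0.74 in lung against RM1536.

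By edgeR, 780 genes passed in RM1536 against RM1, 291 higher and 489 lower; 773 of them differed by 2-fold or more and 46 were predicted or unnamed genes. DESeq2 called 1471 and edgeR without a low-count filter 2394. The count was 486 without RM1 a, 513 without RM1 b, 427 without RM1536 a and 196 without RM1536 b. Of 64 called genes named in the text, 29 kept their call under all alternatives.

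The next comparison asks what distinguishes cells recovered from bone from the cultured line. Padi4, which codes for an enzyme that converts arginine to citrulline in histones, rose in bone by 5.24 ± 0.30 on the log2 scale (adjusted p = 0.0242), from 3.34 and 2.56 CPM to 112; it stood at 14.0 in lung and at 78.4 and 99.6 in RM1. Trp53i11 (chromosome 2, 93187548 to 93201759), a p53-induced gene, had 0 reads in bone against 34.7 and 26.1 CPM in RM1536 and was at least 227-fold lower (adjusted p = 0.0242). It stood at 40.3 CPM in lung and at 2.97 and 2.90 in RM1 (RM1536 against RM1: 3.37 ± 0.27, adjusted p = 0.00704, chosen after its values were seen). These were the 2 genes called in bone against RM1536, and 1372 had an unadjusted p under 0.05. DESeq2 called 379 and edgeR without a low-count filter 859. Without RM1536 a both had an adjusted p of 0.0795 and without RM1536 b of 0.146, and limma-voom called neither (0.0727 and 0.0923). The count was 32 without RM1 a, 128 without RM1 b and 0 without either RM1536 library.

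As groups, interferon-stimulated genes lay lower in bone in 46 of 49 members (median -1.82, camera adjusted p = 2.13e-10), MHC class I genes in 17 of 18 (-0.59, 0.00311) and cell cycle genes in 32 of 32 (-0.55, 0.000226). Collagens and matrix proteins lay lower in 14 of 22 (median -0.85, mean -1.87, 0.000139), epithelial genes higher in 9 of 11 (0.25, 0.0435), and 6 leukocyte markers had a median of 2.23 (0.000127). None of the 6 lists was called with an estimated correlation (adjusted p = 0.880), and 0 members were called over all genes. The leukocyte markers were scarce, with a median level of 2.55 CPM in bone and 0.302 and 0.113 in RM1536. Of the 6, 4 lay higher in bone and 2 lower. The following members were chosen after their values were seen. Laptm5 had 55 reads in bone and 6 and 4 in RM1536, but 46 and 54 in RM1. Adjusted over the list alone, 3 matrix genes were lower: Col1a1, the main type I collagen gene (-4.53 ± 0.85, adjusted p over all genes 0.151), Col5a1 (-1.74 ± 0.37, 0.178) and the tenascin gene Tnc (adjusted p over all genes 0.240). Fn1, the fibronectin gene, had 2770 and 2976 CPM in RM1536 and 780 in bone (-1.88 ± 0.50, 0.274). Ocln (2.39 ± 0.51, 0.178) passed over the epithelial list alone, and 3 leukocyte markers did over theirs, among them Laptm5 (3.70 ± 0.62, 0.120). Stat2, which transmits the interferon signal, had 68.6 and 32.04 CPM in RM1536 and 10.1 in bone (-2.32 ± 0.62, 0.276), and Oas2 had 13.1 and 2.27 against 0.0878 (-6.37 ± 1.62, 0.256). Erap1, which trims peptides for MHC class I, was at -1.15 ± 0.28 (0.230) and the cyclin gene Ccnb2 at -1.27 ± 0.34 (0.286), while Ifitm1 was at 0.81 ± 0.26 (0.365). Among checkpoint ligands (median 0.37, mean -0.03, camera adjusted p = 0.840), 2 were higher and 3 lower over the list alone, the latter including Ulbp1 (-3.49 ± 0.49, 0.0843) and Lgals9 (-3.04 ± 0.55, 0.143).

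Without RM1536 a, the interferon-stimulated list (median -0.45, adjusted p = 0.123) and the MHC class I list (-0.08, 0.291) were not called. Without RM1536 b, the cell cycle list (-0.23, 0.181) and the epithelial list (0.16, 0.302) were not called, and the collagen list was at -0.42 and the MHC class I list at -1.02. The epithelial list was also lost without a filter (0.191) and with the stricter filter (0.0700). Against the mean of RM1 and RM1536, cell cycle (0.194), epithelial (0.563) and collagen lists (0.140) were not called. Without RM1536 a, the leukocyte list was at 3.40, the collagen list at -1.25 and the epithelial list at 0.82. The checkpoint list's median log2 CPM difference was 0.05 for bone minus RM1536 a and 0.79 for bone minus RM1536 b. The remaining 21 lists had camera adjusted p from 0.0675 to 0.985. Of these, over the list alone, 1 mesenchymal gene was lower, 1 lung epithelium marker was higher, and bone metastasis and dormancy lists had 1 higher and 1 lower each. Median, mean and test differed in sign for proteases, bone metastasis, p53, checkpoint, erythroid and endothelial lists.

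For cells recovered from lung, the comparison with the cultured line asks the same question. Cell cycle genes lay lower in lung in 32 of 32 members (median -1.24, camera adjusted p = 2.35e-16) and cholesterol synthesis genes in 20 of 20 (-1.44, 6.92e-11). Matrix proteases and inhibitors lay higher (median 0.62, 13 of 18, 0.00196), as did mitochondrially encoded genes (0.65, 11 of 12, 0.00378), unfolded protein response and ATF4 genes (0.65, 18 of 20, 0.00384), osteoblast and osteoclast markers (1.503, 4 of 6, 0.00260) and leukocyte markers (1.39, 5 of 6, 0.00306). With an estimated correlation none of the 7 was called (adjusted p = 0.826 for the unfolded protein response and 0.817 for the other lists). No gene was called by edgeR: 0 of 13832, with 1902 at an unadjusted p under 0.05, 0 calls by limma-voom, 351 by DESeq2 and, in lung against RM1536, 1299 by edgeR without a low-count filter. The smallest adjusted p was 0.0759, for Crip2 (4.38 ± 0.29), which was chosen after its values were seen.

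The lung examples that follow were also chosen after their values were seen, and none passed over all genes. The 6 leukocyte markers were scarce, with a median level of 1.82 CPM in lung and 0.302 and 0.113 in RM1536. So were the 6 osteoblast and osteoclast markers, with a median of 1.16 CPM in lung and 0.262 and 0.275 in RM1536. Adjusted over the list alone, 10 cholesterol synthesis genes were lower. Idi1 was at -2.44 ± 0.56 (adjusted p over all genes 0.295), with 161 and 276 CPM in RM1536 against 40.1, Hmgcs1 at -2.03 ± 0.58 (0.317) and Cyp51 at -1.41 ± 0.33 (0.295). Thymidine kinase gene Tk1 was at -2.72 ± 0.70 (0.298), Cdc20 at -1.69 ± 0.47 (0.308) and Pcna at -1.05 ± 0.36 (0.326). Over the protease list alone 5 genes were higher and 1 lower: the collagenase gene Mmp13 was at 2.47 ± 0.62 (0.297), Mmp10 at 3.29 ± 0.86 (0.303), Mmp3 at 2.02 ± 0.60 (0.320), the lysosomal protease gene Ctsl at 1.64 ± 0.40 (0.297) and Plat at -1.28 ± 0.30 (0.295). Over their lists alone, 3 osteoblast and osteoclast markers were higher, among them the osteoclast protease gene Ctsk (3.19 ± 0.70, 0.295) and Phex (1.46 ± 0.34, 0.295), and 2 leukocyte markers. Col1a1 stood at 604 CPM in lung against 8.85 and 27.8 in RM1536 (5.04 ± 0.62, 0.252) and was the matrix gene higher over its list alone. Ptgs2, which codes for the prostaglandin synthase COX-2, was at 2.42 ± 0.54 (0.295), mt-Cytb had 2345 and 2196 CPM against 5037, Cth was at 2.32 ± 1.05 (0.396), and Cd276 passed over the checkpoint list alone (1.09 ± 0.24, 0.295; list camera adjusted p = 0.0513).

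The interferon-stimulated list in lung (median -0.74, 41 of 49 lower) was not called (camera adjusted p = 0.136, 0.889 with an estimated correlation). Without RM1536 a it was called higher (median 0.93, adjusted p = 3.42e-07) and without RM1536 b lower (-1.47, 3.89e-29). Without RM1536 b, the unfolded protein response list (median 0.35, 0.315) and the leukocyte list (0.57, 0.0573) were not called, and the cholesterol list was at -0.86. Without RM1536 a the leukocyte list was at 2.72 and the unfolded protein response list at 1.19. Without a filter, the unfolded protein response (0.0579) and osteoblast lists (0.169) were lost. The count of called genes was 7 without RM1 b. Median, mean and test differed in sign for receptors and sensors, bone metastasis and endothelial lists, and the remaining lists had adjusted p up to 0.959. Over the p53 list alone 1 gene was higher.

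Bone and lung were set against each other to ask which differences go with the site, although each site is 1 library. Trp53i11 had 0 reads in bone and 40.3 CPM in lung, at least 306-fold lower (adjusted p = 0.0443), and was the 1 gene called in bone against lung, with 1171 at an unadjusted p under 0.05. DESeq2 called 218 and edgeR without a low-count filter 754. Its adjusted p was 0.0835 without RM1536 a and 0.0663 without RM1536 b, 0.0666 under the stricter filter and 0.276 by limma-voom, and 1 other gene was called in each of the leave-outs of RM1536. The count was 32 without RM1 b. In descriptive values, Krt20, an epithelial keratin gene (chromosome 11, 99428403 to 99438150), had 645 reads in bone and 2 in lung, a ratio of 359 (95% counting interval 98.9 to 2969), and Cd24a had 159 and 1 (177, 31.3 to 7030). Higher in bone were also Slc6a4 (15.02 against 0.158 CPM), St8sia4 (13.7 against 0.158), Tbc1d30 (21.8 against 0.474), Spx (53.7 against 1.26), the tight junction genes Ocln (6.37 against 0.158) and Cldn6 (87.2 against 3.51), Fst (8.74 against 0.434) and Wfdc13 (21.4 against 1.26). Lower in bone were Col1a1 (chromosome 11, 94936224 to 94953042; 0.791 against 604), Gata4 (0 reads, at least 45.8-fold), Cox6a2 (0.044 against 15.6), Bgn (0.088 against 25.3), Car6 (0.395 against 109), Zfp521 (0.044 against 11.7), Sh2d6 (0.176 against 28.1), Pde10a (0.088 against 13.3) and Rcn3 (0.132 against 10.9). Of these, Car6 also differed between RM1 a and b (0.2 and 24.8 CPM). Fn1 stood at 780 CPM in bone and 5295 in lung, and Ulbp1, chosen after its values were seen, at 0.791 and 13.6 (-4.10 ± 0.52, adjusted p = 0.150).

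As lists, cholesterol synthesis genes stood higher in bone than in lung in 20 of 20 members (median 1.15, percentile 100 of random lists) and cell cycle genes in 30 of 32 (0.77, percentile 100). Unfolded protein response genes stood lower in 18 of 20 (-0.85, percentile 0), interferon-stimulated genes in 42 of 49 (-1.19, percentile 0), proteases in 14 of 18 (-0.65, percentile 0), MHC class I genes at -0.50 (0.03), mesenchymal genes at -0.57 (0.01), NRF2 genes at -0.43 (0.1), stromal markers at -0.70 (0.3) and checkpoint ligands at -0.59 (0.53; over the list alone 2 higher and 4 lower). Epithelial genes stood at 0.69 (98.7), glycolysis genes at 0.26 (99.6), MYC targets at 0.20 (98.5), p53 targets at 0.29 (98.0) and collagens at -0.25 (3.59), and the other lists lay between percentiles 4.59 and 84.6. Over the list alone, 1 epithelial gene and 1 leukocyte marker were higher in bone, 1 collagen list member (Col1a1) and 1 osteoblast or osteoclast marker were lower, and bone metastasis genes had 1 of each. For some of these lists, differences of the same sign lay between culture duplicates. The RM1 a minus b medians were 0.52 for cholesterol synthesis, 0.81 for the cell cycle and -0.98 for the unfolded protein response. The RM1536 b minus a medians were 0.88, 0.63 and -0.89. In these 2 pairs, interferon-stimulated genes were at -0.49 and -2.59, proteases at -0.18 and -0.76 and MHC class I genes at -0.28 and -0.73. Stromal markers were at -0.85 and -0.74, checkpoint ligands at -0.50 and -0.50 and MYC targets at 0.09 and 0.49. Mesenchymal (0.03 and 0.11), NRF2 (0.17 and 0.04) and collagen genes (0.37 and 0.61) went against bone minus lung in both pairs. Epithelial, glycolysis and p53 lists had mixed signs. Across genes, bone minus lung correlated with RM1 a minus b at r = 0.385 and with RM1536 b minus a at 0.256; genes are not independent replicates, and the letters were put in this order after the values were seen. Median and mean differed in sign for receptors and sensors, leukocyte and endothelial lists, and the erythroid list had a median of 0 and a mean of 0.58.

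**Figure D4:**
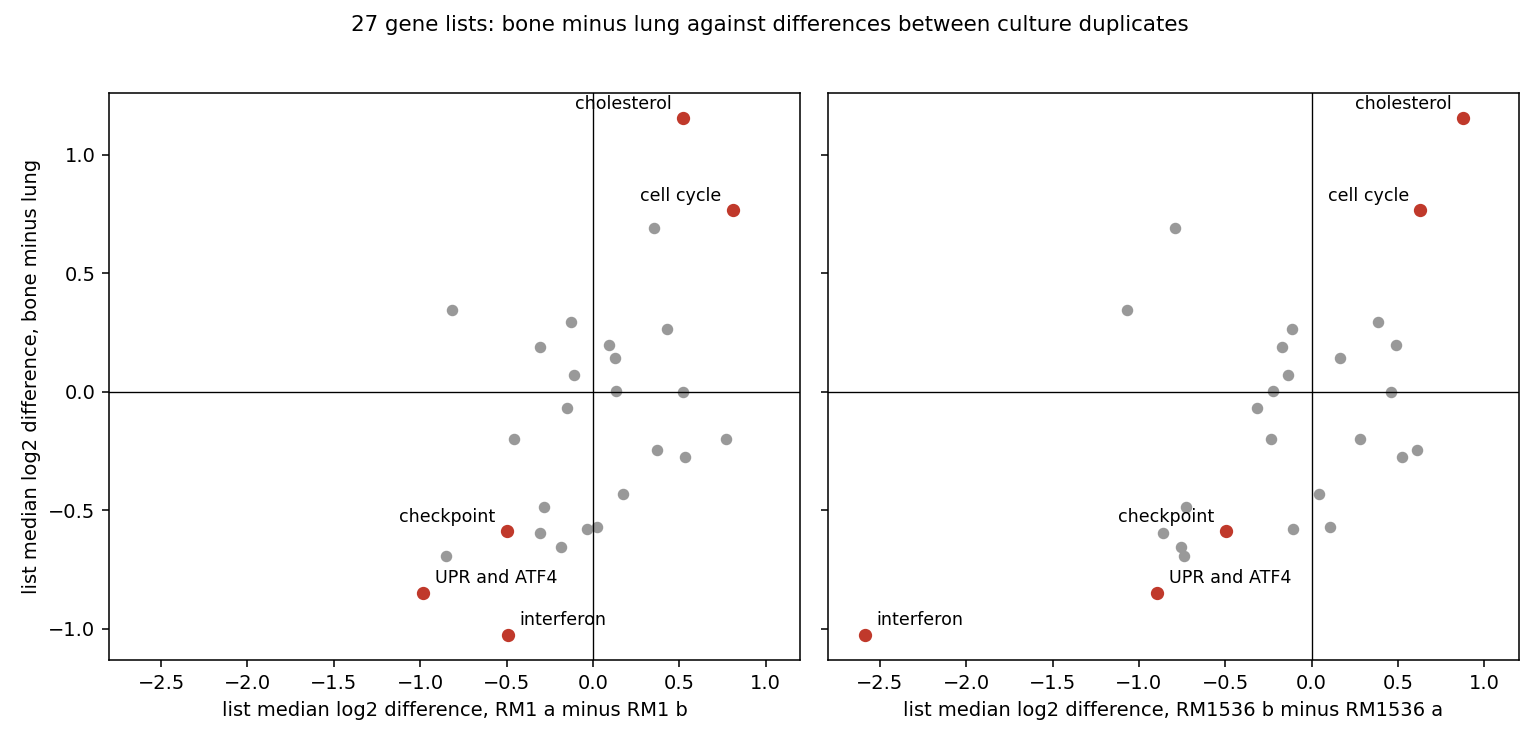
Median log2 difference of the 27 gene lists between bone and lung (vertical axis) against the difference between RM1 a and b or RM1536 b and a (horizontal axes). Cell cycle and cholesterol lists lie above 0 and the unfolded protein response list below 0 on all axes.

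Bone and lung were both compared with the same 2 RM1536 libraries, which by itself makes their fold changes alike. Across 13832 genes the correlation of the log2 fold changes was 0.425, against 0.305 (0.258 to 0.344 in 40 draws) in tables simulated with no change and shared controls. The covariance was 0.561 against 0.144 (0.123 to 0.162). Lung had 0 called genes, so calls could not overlap. The same sign was seen in 66.3% of genes, against 61.0% in simulation. With 1 RM1536 library for each site, in log2 CPM, the correlation was 0.127 (covariance 0.119) with RM1536 a for bone and b for lung. It was 0.367 (0.282) with the reverse, against 0.427 (0.319) with the mean of both. Over genes at a mean CPM of at least 5, these values were 0.057 (0.034), 0.415 (0.188) and 0.415 (0.190), in the same order. This split was chosen after the values were seen, and each site then has 1 control library. The simulated tables hold the shared controls too, so the excess is over their part as simulated. With separate controls the covariance stayed positive both ways, but its size depended on which library went with which site. The simulation drew each gene independently, while genes moved together between the duplicates. Its range may therefore be too narrow, and the excess cannot be read as a shared response.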

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

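All tests of explanations in this part were chosen only after the result was seen. Trp53i11 passed in bone against lung (adjusted p = 0.0443), a test of 1 library against 1 with the spread taken from the culture duplicates. Its call ended under 5 of 12 alternatives: limma-voom (0.276), the replicate block (0.244), without RM1536 a (0.0835) or b (0.0663), and the stricter filter (0.0666). Near it on chromosome 2, Syt13 had 0 reads in bone, 33 and 25 in RM1536 and 27 in lung. Prdm11 had 23 in bone, 166 and 259 in RM1536 and 110 in lung. Ext2 (log2 fold change 0.16 in bone against RM1536) and Cd82 (1.34) were not lower. These neighbours were chosen after their values were seen, and none was called in bone against RM1536. In addition, 8 untested, scarce genes had at least 3 reads in bone and in lung each. They had at most 1 read in the 4 cultures together. Summed over bone and lung these were Adgre1 with 9 reads, Apela with 12, Ccl6 with 13, H2-Eb1 with 11, Jsrp1 with 7, Ms4a6d with 8, Wfdc17 with 10 and Xist with 11. Adgre1, Ccl6, H2-Eb1, Ms4a6d and Wfdc17 are expressed by myeloid or antigen-presenting cells. In the other direction, with at least 3 reads in both libraries of a culture group and at most 1 in bone and lung together and in the other culture group together, there were 77 genes for RM1 and 19 for RM1536. These counts hold any real differences between the groups and are no measure of chance, which was not tested.

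Interferon-stimulated genes stood higher in RM1536 a than in RM1536 b, with a median log2 difference of 2.59. RM1 cells or RNA mixed into RM1536 a would need a share of 18.8% by the interferon genes, while 11 genes outside the lists, abundant in RM1 and nearly silent in RM1536 b, stood in RM1536 a at a median of 3.86% of their RM1 level: Iigp1 24.5%, Apol9a 16.1%, Apol9b 16.03%, Selp 11.4%, Gm20559 9.69%, Prss22 3.86%, Sp100 1.35%, Trim54 0.730%, Csn3 0.144%, Peg3 -0.05% and Cdkn2b -0.06%. Iigp1, Apol9a, Apol9b and Sp100 are themselves inducible by interferon, so the median over the 11 genes is no estimate of admixture. Admixed RM1 would bring its abundant transcripts alike. Cdkn2b, Csn3, Peg3 and Trim54 stood at 0.730% or less, against the 18.8% needed. These levels argue against admixture as more than a small part of the source. Over all tested genes at a mean CPM of at least 5, the median a minus b difference was 0.00223. TMM scaling itself brings this value near 0, so it cannot decide on scaling. Relative to that median, the interferon genes stood higher in RM1536 a. A different interferon state of the cultures, or a different mix of the pooled clones, may be the source and stays open, because no sample of a single clone was measured.

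Cell cycle and cholesterol lists stood higher and the unfolded protein response list lower in bone than in lung, and the same lists differed between culture duplicates. GC content and transcript length are argued against, because the 3 medians kept at least 90.3% of their size after that trend was removed. After thinning to equal depth, at least 99.5% was kept. Bone is itself the smallest library, and thinning hardly moves the CPM of abundant genes, so this test cannot decide on depth. A state of the culture or library that the site did not set would make bone minus lung correlate with the duplicates' differences. Across genes, r was 0.385 with RM1 a minus b and 0.256 with RM1536 b minus a. All 3 list signs went along in both pairs. These signs were seen beforehand and the order of the letters was free, so they are no independent support. Such a state may account for part of the difference between bone and lung. The labels give the same confluence, 85%, for all 6 libraries. A difference set by the site stays open, since each site is 1 library of 1 mouse.

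Lyz2, an abundant myeloid gene, had 0 reads in the 4 cultures, 61 in bone (2.68 unscaled CPM, 2.05 to 3.44) and 73 in lung (2.71, 2.13 to 3.41). Host leukocytes carried through the sort and culture may be the source: the 12 other leukocyte markers with at most 100 reads in total were 3.03 times as frequent in bone and lung as in culture (counting interval 2.22 to 4.15), at 1.93 and 2.04 reads per 1e6 counts against 0.218 to 0.990 in the cultures. Without Cd74 (14 and 19 reads) the ratio was 2.26 (1.58 to 3.23), and Ptprc had 0 and 0 reads, Csf1r 5 and 4, and Coro1a 6 and 4 against 9, 1, 1 and 9 in the cultures. The 3 listed markers above the limit were mixed. Cd14 had 337 and 375 reads in bone and lung, against 694, 651, 455 and 592 in the cultures. Cd68 had 449 and 511 against 287, 1230, 279 and 111, and Laptm5 had 55 and 7 against 46, 54, 6 and 4. The sort for eCFP-positive, PKH-negative cells would remove leukocytes, and carry-over between libraries of a run and low expression in the tumour cells were not tested.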

How the results depend on the processing

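The tests with crossed pairing of culture libraries, and the counts of called lists with 1 library left out, were chosen after seeing the data. In RM1536 against RM1, 780 genes were called. There were 2394 without a low-count filter, 426 with the stricter filter, 1471 by DESeq2, 250 with the replicate letter as a block, 3318 with the crossed block and 196 to 513 with 1 culture library left out (fewest without RM1536 b). DESeq2 size factors (814), limma-voom (857), robust dispersion (765) and the 4 culture libraries alone (836) stayed within 1.5 times. Of the 780, 760 were also called by DESeq2, 740 by limma-voom, 426 with the stricter filter and 245 with the block. Of 64 named genes called, the calls of 5 ended by DESeq2, 3 by limma-voom, 7 of 57 with the stricter filter, 27 with the block, and 14, 13, 20 and 28 without RM1 a, RM1 b, RM1536 a and RM1536 b. No named gene changed direction under a setting that was run.

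For bone against RM1536, the 2 calls became 859 without a filter, 379 by DESeq2, 0 by limma-voom, 0 with the block, 969 with the crossed block, 194 against the mean of RM1 and RM1536, and 0 to 128 with 1 library left out. Padi4 and Trp53i11 had an adjusted p of 0.112 with the block. For lung against RM1536, the 0 calls became 1299 without a filter, 351 by DESeq2, 1945 with the crossed block, 78 against the mean reference and 0 to 7 with 1 library left out. For bone against lung, the 1 call became 754 without a filter, 0 with the stricter filter, 218 by DESeq2, 0 by limma-voom, 0 with the block, 934 with the crossed block and 1 to 32 with 1 library left out. The cause of these differences was not tested.

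Gene lists called were 7, 6 and 7 in the 3 comparisons with RM1 or RM1536. With an estimated correlation 0, 0 and 0 were called (smallest adjusted p 0.911, 0.880 and 0.817), and with the directional fry test 0, 0 and 0 (0.380, 0.605 and 0.205). The mixed fry test, which counts changes either way, called 10, 0 and 0 (smallest adjusted p 0.0101, 0.0640 and 0.0748). With 1 library left out, 5 to 11 lists were called in RM1536 against RM1, 5 to 8 in bone and 7 to 10 in lung. In simulated tables with planted changes, 14% of 2-fold changes were called between the cultures and 2.67% between single libraries.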

Other observations

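The counts in this part were chosen only after the values were seen, and no tests of explanations were run on them. Some abundant genes were nearly silent in another group. Of 8500 genes at 10 CPM or more in both RM1 libraries, 6 stood at 1% or less of that level in both RM1536 libraries, and the same 6 did in bone and lung: Csn3, Peg3, Enox2, Msx1, Xlr and Cdkn2b. Enox2 had 12.9 and 13.0 CPM in RM1 and 0 reads in the other 4 libraries, and Xlr had 15.2 and 14.0 CPM and 0. Of 8412 genes at that level in RM1536, 2 were silent in RM1 (Ptgis and Dkk2), 4 in bone (Dapk1, Pde10a, Trp53i11 and Fam217b) and 1 in lung (Dapk1). Dapk1, a death-associated kinase gene, stood at 140 and 86.1 CPM in RM1, 12.3 and 57.5 in RM1536, 0.044 in bone and 0.118 in lung. Myc, the transcription factor gene, stood at 38.4 and 15.2 CPM in RM1536, 8.34 in bone and 124 in lung.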
